A study of Homo sapiens with 6 samples.

How the data were processed

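Gene expression was measured by RNA-seq of total RNA from 6 libraries of HuES8 cells differentiated to definitive endoderm, 3 wild type (DE) and 3 with GATA6-AS1 knocked down (KD), as the sample titles name them. The means of knockdown, and whether the wild-type cells carried a control construct, are not given in the sources used here. The authors deposited 1 table of TPM for 58830 genes, in which each of the 6 columns sums to 1000000, per the file headers and the values. The submitters' processing notes name HISAT2 2.1.0, featureCounts, DESeq2 and the build GRCh38, without saying which step used each. The annotation release, the strand setting and any filter are not given in the sources used here. TPM relate each gene to the total of its library, so a larger share of one class of RNA lowers every other value. Reads that overlapping or antisense genes share could not be told apart. In 28 rows the gene symbol had turned into a date, and 4 rows shared 2 such names; these rows stayed in the tests and are not named.

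TPM keep no depth. For the 37138 rows matched by symbol to 1 gene of GENCODE release 29, TPM was multiplied by the summed exon length, and low values (under 50 reads) were compared with whole multiples of 1 constant per library. Between 88.2% and 89.0% lay within 0.02 of a whole number of reads, which gave the estimated reads per library. These estimates served only to describe depth, in 1 added alternative and to set the depth of the simulated data. Coordinates are those of GENCODE 29 on GRCh38, 1-based.

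Genes with at least 1 TPM in at least 3 of the 6 libraries were tested. The values were log2(TPM + 1), so a fold change is on the scale of TPM plus 1 and understates the change of low genes. The linear model of limma 3.58.1 in R 4.3.3 with group as its term and eBayes with trend gave 2-sided moderated p-values, adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. All adjusted p-values of single genes are limma's. GATA6-AS1 and GATA6 also had an exact permutation test of the 3 against 3 TPM values. The 30 gene lists with at least 5 tested members were tested by camera with a preset inter-gene correlation of 0.01 and adjusted over the lists. Members were also counted after adjustment over the list alone. None of the 30 lists passed when camera estimated the correlation for each list from these 6 libraries. All 30 then had the same adjusted p, 0.994, which does not rank them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the rest.

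The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took GATA6-AS1 and GATA6. It also took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with a mean of at least 5 TPM in the higher group, a gene symbol and no overlap between the groups. It further took 12 markers (SOX17, FOXA2, CXCR4, GATA4, EOMES, GSC, CER1, POU5F1, NANOG, SOX2, T and MIXL1) and up to 4 members of each list with the smallest p. APLNR, GRHL2 and BMP2, named to complete small counts, fall outside the rule and were chosen after their values were seen. Some genes that the rule takes are not reported here.

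The sample titles number the replicates 1 to 3 in both groups. After the group means were removed, same-numbered DE and KD libraries correlated over genes at 0.108, 0.144 and 0.347, all above the 0.1 set as the limit for treating the numbers as pairs. The first pair passed narrowly, since DE replicate 2 and KD replicate 1 correlated at 0.121 and the first pair at 0.0973 without mitochondrial genes. Values with the replicate number as a block are therefore given beside the results they change. The pairing rests on this check of the data and not on a label. Deviations from a group mean cancel out over the libraries of the group. A shift shared by the third replicates alone therefore raises every correlation among replicates 1 and 2, matched or not. The unmatched DE replicate 1 and KD replicate 2 correlated at 0.0769. The check could thus not tell whether replicates 1 and 2 were paired, and values with the block assume that they were.

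The alternatives were other pseudocounts (0.1 and 0.5), other filters (none, or a mean of 5 TPM), quantile and median-ratio scaling, limma without the trend or with robust variance, stricter thresholds, the replicate block, leaving out each library, and for lists an estimated correlation or fry. After the data were seen, TPM recomputed without mitochondrial genes, a fit without replicate 3 of both groups, limma's voom on the estimated reads, and camera with both an estimated correlation and the block were added. On data simulated for KD against DE over 14864 genes, the fit recovered 6% of genes changed by 0.5 on the log2 scale, 65.7% of those changed by 1 and 95.5% of those changed by 2, with 11 false calls among 14664 unchanged genes. The simulated noise was independent between genes and libraries. It held no shift shared by many genes, such as that of replicate 3 described below, so these figures may not hold for the real libraries.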

Results

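RNA-seq was carried out on definitive endoderm made from HuES8, a human embryonic stem cell line. The cells had been differentiated for 3 days in DMEM-F12 with 0.2% BSA, first with 100 ng/mL Activin A and 2.5 µM CHIR (a GSK3 inhibitor that activates Wnt signalling) for 1 day and then with Activin A alone for 2 days. The 6 libraries, made from total RNA, fell into 2 groups of 3, wild-type endoderm (DE) and endoderm with GATA6-AS1 knocked down (KD). The values were TPM, read counts scaled for gene length and library total, for 58830 genes. The authors' TPM values keep no depth of their own, and the reads behind them were estimated from the steps between low values at 23759569, 22222000 and 18990986 for DE replicates 1 to 3 and 18640821, 21525253 and 24510594 for KD replicates 1 to 3. At these depths 1 TPM of a 2 kb gene stood for between 11.28 and 16.16 reads. Transcripts encoded by mitochondrial DNA took 28.5%, 24.6% and 38.04% of TPM in the DE libraries and 28.3%, 28.8% and 36.2% in the KD libraries, so replicate 3 lay apart in both groups. Nothing in the labels said that replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

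The title of the series concerns the control of GATA6 by its antisense RNA during endoderm differentiation, and the knocked-down RNA was examined first. GATA6-AS1 stood at 389, 421 and 313 TPM in the DE libraries and at 180, 163 and 126 TPM in the KD libraries. Its mean was 374 ± 55.1 TPM in DE and 157 ± 27.3 TPM in KD (SD, n = 3 each), a log2 change of -1.26 (SE 0.164). Every KD library lay below every DE library. The KD mean was 0.418 of the DE mean. The fall passed the test over all genes (limma adjusted p = 0.0128), and the 2-sided exact permutation test gave 0.1, the smallest p that 3 against 3 libraries allow. Without DE replicate 1 or KD replicate 2 the log2 change was -1.22 or -1.30 and the limma adjusted p was 0.0717 or 0.0612.

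GATA6, the zinc-finger transcription factor required for definitive endoderm, had 346 ± 52.8 TPM in DE and 218 ± 30.6 TPM in KD (SD, n = 3 each). The libraries held 367, 385 and 286 TPM in DE and 251, 211 and 191 TPM in KD, without overlap between the groups. The log2 change was -0.66 (SE 0.150, 95% interval -1.01 to -0.31). It did not pass the test over all genes (limma adjusted p = 0.0648), and passed it with the replicate number as a block (limma adjusted p = 0.00500). The exact permutation p was again 0.1. In the GENCODE 29 annotation of GRCh38, GATA6-AS1 (ENSG00000266010.2) lies on chromosome 18 from 22164886 to 22169878 on the minus strand, and GATA6 (ENSG00000141448.8) from 22169443 to 22202528 on the plus strand. The gene spans overlap by 436 bases, of which 240 are exonic in both genes, 7.56% of the exon length of GATA6-AS1 and 6.08% of that of GATA6. The strand setting of the counting is not given in the sources used here, so reads from these shared bases could not be assigned to either gene. The list of the GATA6 region on chromosome 18, with 14 tested genes that include GATA6 and GATA6-AS1, held 1 gene that passed, GATA6-AS1 (1 higher and 2 lower with the replicate block, the 2 being GATA6-AS1 and GATA6), and the list did not pass (camera adjusted p = 0.891). Its median log2 change was 0.03 and its mean -0.04.

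**Figure D1:**
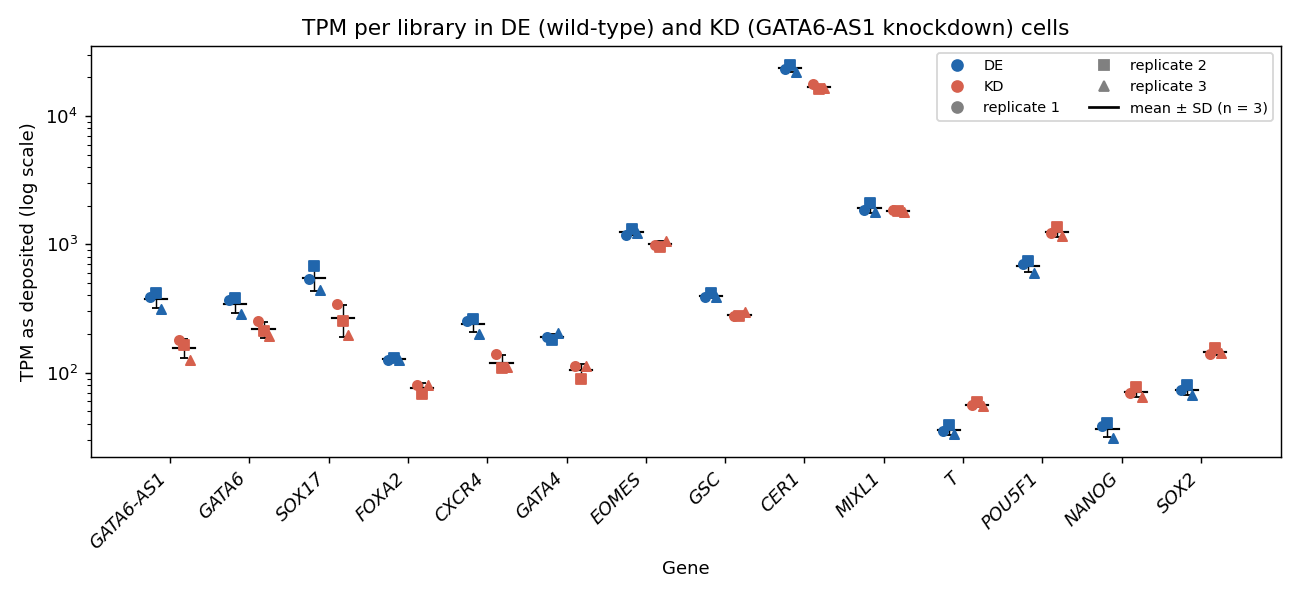
TPM as deposited (log axis) of GATA6-AS1, GATA6 and 12 marker genes in each library of DE (blue) and KD (red) cells, with the marker shape giving the replicate and black bars the mean ± SD (n = 3). GATA6-AS1 was at 313 TPM or more in the DE libraries and at 180 TPM or less in the KD libraries, while the MIXL1 values of the groups overlapped.

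The comparison of all genes asked which transcripts differed between KD and wild-type endoderm. KD cells had more RNA of stem cell factors and less of endoderm regulators. Of 17711 genes tested, 579 passed an adjusted p of 0.05, 314 higher and 265 lower in KD. LINC00678, a stem cell long noncoding RNA, rose from 22.8 ± 1.34 to 132 ± 9.58 TPM (SD, n = 3 each), a log2 change of 2.48. ESRG, a long noncoding RNA of pluripotent cells derived from an endogenous retrovirus, rose from 130 ± 6.33 to 480 ± 22.3 TPM. CCKBR, the gastrin and cholecystokinin receptor, fell from 198 ± 23.2 to 71.8 ± 13.5 TPM, a log2 change of -1.46.

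Among genes of at least 5 TPM in the higher group, the 10 with the largest rise also held SPP1, which encodes the secreted protein osteopontin, at 3.44 ± 0.0900 TPM in DE and 17.5 ± 3.22 TPM in KD (SD, n = 3 each). HES3, a basic helix-loop-helix repressor, rose from 1.08 ± 0.411 to 7.47 ± 3.27 TPM. The others were VAT1L, TRIML2, SYT6, VSNL1, OLFML3 and MIR4254, with log2 changes from 1.92 for OLFML3 to 2.47 for MIR4254. The 10 with the largest fall held RNASE1, a secreted ribonuclease, at 24.1 ± 0.802 TPM in DE and 7.93 ± 0.846 TPM in KD. VWF, the von Willebrand factor, fell from 33.8 ± 4.44 to 12.5 ± 1.73 TPM, and EYA2, a transcriptional coactivator, from 30.7 ± 1.10 to 11.8 ± 1.01 TPM. DACT2, an antagonist of dishevelled, fell from 44.6 ± 3.23 to 17.6 ± 3.58 TPM. CLDN11, ACSM4, NCR1, LINC01612 and MIRLET7I completed this set, with log2 changes from -1.53 for MIRLET7I to -1.28 for LINC01612. MIR4254 and MIRLET7I are short precursor features for which few reads make many TPM, and ESRG and LINC00678 may share reads with related retroviral copies, so their values are less certain.

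The limma adjusted p of these 20 genes ran from 0.000438 for LINC00678 to 0.0379 for MIR4254. With the replicate number as a block, 2215 genes passed, 1042 higher and 1173 lower, and all 579 genes were among them in the same direction. The count varied with the library left out, with fewer libraries in each fit. Without DE replicate 1, 2 or 3 it was 99, 212 or 610. Without KD replicate 1, 2 or 3 it was 170, 87 or 252. It was 1212 without replicate 3 of both groups, and between 1696 and 1743 when TPM were rescaled by quantiles, by median ratios or without mitochondrial genes.

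**Figure D2:**
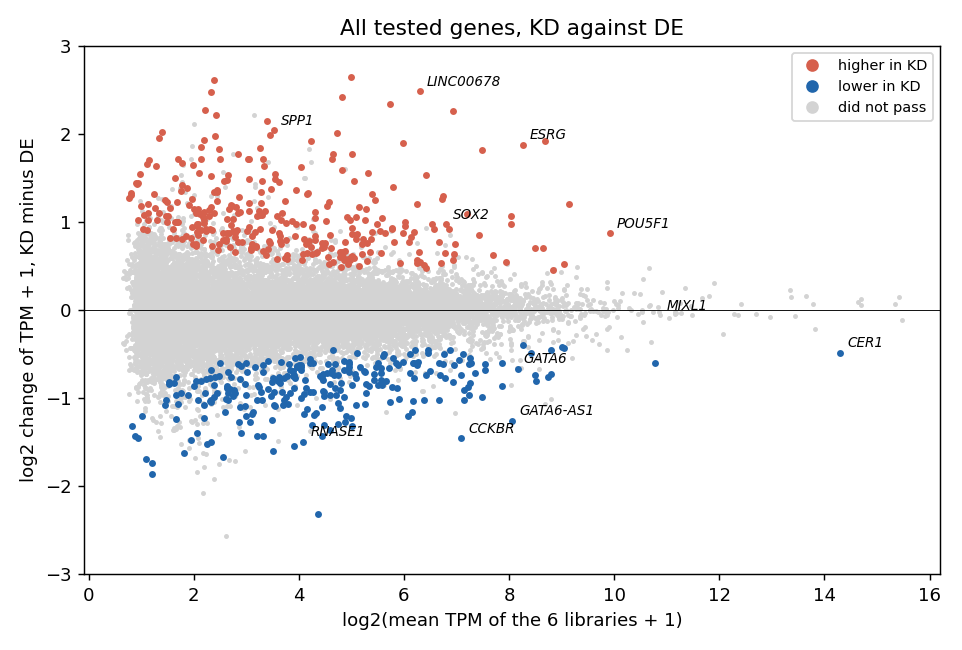
Log2 change of TPM + 1 (KD minus DE) of the 17711 tested genes against the log2 of their mean TPM over 6 libraries + 1, with genes at an adjusted p below 0.05 in red (314 higher) or blue (265 lower) and the rest in grey. LINC00678 and ESRG lie far above 0 and CCKBR and GATA6-AS1 far below it; 1 gene that did not pass (AL353644.11) lies outside the plotted range.

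Definitive endoderm genes were lower in KD as a group. Of 35 list members tested, 18 fell, none rose and 17 did not pass, with a median log2 change of -0.70. FOXA2, a pioneer factor of endoderm, fell from 127 ± 2.21 to 76.0 ± 6.59 TPM (SD, n = 3 each), and the chemokine receptor CXCR4, a surface marker of definitive endoderm, from 238 ± 31.4 to 120 ± 18.3 TPM. GATA4 fell from 191 ± 11.3 to 104 ± 13.6 TPM and OTX2, a homeobox factor of anterior endoderm, from 450 ± 9.20 to 270 ± 18.4 TPM. CER1, a secreted Nodal antagonist, fell from 23570 ± 1560 to 16815 ± 773 TPM, a log2 change of -0.49.

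GATA3 (log2 change -1.20), PLXNA2 (-0.87) and GSC (-0.49) also fell. The limma adjusted p of the endoderm genes named here and of CCKBR lay between 0.00606 for CCKBR and 0.0406 for CER1. SOX17, an endoderm transcription factor, had 551 ± 115 TPM in DE and 265 ± 73.3 TPM in KD and did not pass (log2 change -1.07, limma adjusted p = 0.0530, with the replicate block 0.00757). EOMES, a T-box factor that acts upstream of SOX17, had 1239 ± 67.1 and 1002 ± 61.5 TPM and did not pass either (log2 change -0.31, limma adjusted p = 0.132, with the replicate block 0.0368). Adjusted over the list alone, 30 members fell, and with the replicate block over all genes 30 fell. The list passed against the other genes (camera adjusted p = 9.96e-24). With an estimated correlation its camera p was 0.0339 unadjusted and 0.994 adjusted, the adjusted value that all lists shared. Over all genes, 1 member fell without DE replicate 1, 9 without DE replicate 2, 11 without KD replicate 1 and 2 without KD replicate 2, while the list's median stayed between -0.77 and -0.61 without any single library.

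Pluripotency genes were higher in KD as a group. Of 28 list members tested, 13 rose, none fell and 15 did not pass, with a median log2 change of 0.60. POU5F1, which encodes OCT4, rose from 682 ± 78.3 to 1247 ± 105 TPM (SD, n = 3 each), SOX2 from 73.8 ± 6.71 to 146 ± 8.73 TPM and NANOG from 36.6 ± 5.06 to 70.5 ± 6.02 TPM. These core factors of the stem cell state had log2 changes of 0.87, 0.98 and 0.93 and limma adjusted p of 0.0131, 0.00587 and 0.0147. DPPA2, a chromatin factor of pluripotent cells, rose from 5.14 ± 0.608 to 16.2 ± 1.51 TPM, and the surface glycoprotein THY1 from 13.04 ± 1.55 to 41.4 ± 3.61 TPM. A total of 18 members rose and 1 fell when adjusted over the list alone, and 19 and 1 with the replicate block over all genes. The list passed (camera adjusted p = 5.65e-15). With an estimated correlation its camera p was 0.0789 unadjusted and 0.994 adjusted. Without DE replicate 1, KD replicate 1 or KD replicate 2, 5 members rose over all genes, and the median lay between 0.47 and 0.68 without any single library.

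Single primitive streak genes passed in both directions. Of 17 members tested, 3 rose, 2 fell and 12 did not pass. GDF3, a TGF-beta family ligand, rose from 61.3 ± 7.84 to 151 ± 9.85 TPM (SD, n = 3 each), FGF4 from 61.9 ± 11.6 to 121 ± 9.07 TPM and T, the brachyury gene, from 35.8 ± 2.95 to 56.4 ± 2.06 TPM. GSC and APLNR fell. MIXL1, a homeobox gene of the streak and mesendoderm, had 1907 ± 163 TPM in DE and 1824 ± 39.6 TPM in KD, a log2 change of -0.06 with a 95% interval of -0.27 to 0.15. The list had a median log2 change of -0.04 and a mean of 0.03 and did not pass (camera adjusted p = 0.957). In counts adjusted over the list alone, 5 members rose and 5 fell, and likewise 5 and 5 with the replicate block over all genes. Over all genes no member fell without DE replicate 1 or 2 or without any one KD library, and 1 rose without DE replicate 1, KD replicate 1 or KD replicate 2 and 2 without KD replicate 3.

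Among the lists of other cell types that the culture could hold, camera passed yolk sac and visceral endoderm, which was lower in KD. Of 14 genes of that list, 3 fell and none rose. APOA2 fell from 5.47 ± 1.06 to 1.73 ± 0.129 TPM (SD, n = 3 each), APOE from 512 ± 20.6 to 373 ± 2.89 TPM and COL4A1 from 157 ± 15.7 to 105 ± 2.80 TPM, the first pair encoding apolipoproteins and the last a basement membrane collagen. Adjusted over the list alone 7 fell, as did 7 with the replicate block over all genes, but 0 members passed without DE replicate 1, DE replicate 2, KD replicate 1 or KD replicate 2, and 1 without KD replicate 3. The list passed (camera adjusted p = 7.10e-06), with an adjusted p = 0.994 with an estimated correlation and 0.0954 by fry (0.0491 by fry with the replicate block). Trophoblast and amnion genes split, with GATA3, HAND1 and ERVW-1 lower and GATA2 and TFAP2C higher among 8 tested (camera adjusted p = 0.148); this list passed by fry (adjusted p = 0.0394, median log2 change -0.46). Among 13 mesoderm genes TBX5 and KDR rose and HAND1 fell (camera adjusted p = 0.129). HAND1, a factor of extraembryonic and lateral mesoderm, went from 4.30 ± 0.552 to 0.746 ± 0.362 TPM. Among 13 gut tube genes 2 rose, SOX9 and SOX2, and 1 fell (0.118), and among 14 neuroectoderm genes SOX2 rose and DLK1 fell (0.891). Fibroblast feeder genes (0.298), mesenchymal genes (0.340) and collagen and matrix genes (0.118, but 0.0379 with voom) did not pass, the numbers in brackets being camera adjusted p. With the replicate block over all genes, more members passed: 2 rose and 3 fell in mesoderm, 3 and 4 in neuroectoderm, 3 and 5 in the mesenchymal list, 2 and 7 in collagens and matrix, 2 and 4 in trophoblast and amnion, 2 and 2 in gut tube and 1 and 2 in fibroblast feeder. Without DE replicate 1 no trophoblast and amnion gene passed, and no mesoderm, gut tube or neuroectoderm gene fell. Without any one KD library no trophoblast and amnion gene rose. The fall in gut tube also did not pass without DE replicate 2, KD replicate 1 or KD replicate 2, nor that of DLK1 without DE replicate 2 or KD replicate 2, and no mesoderm gene rose without KD replicate 2 and 1 without any other single library.

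**Figure D3:**
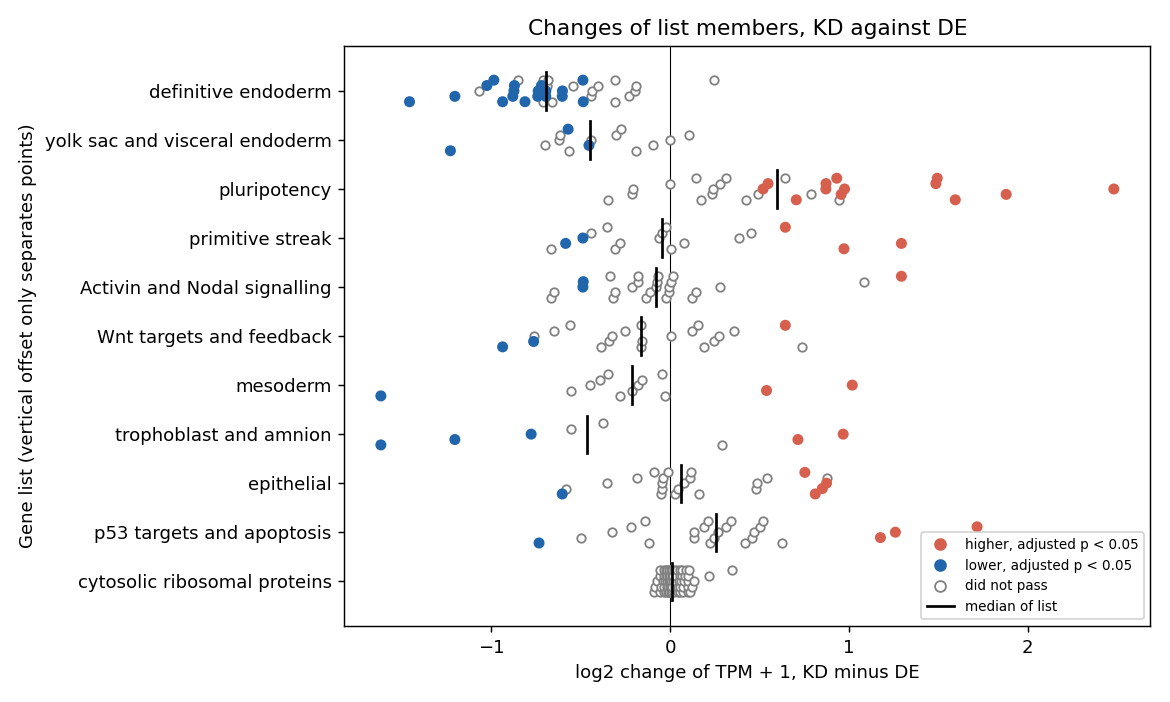
Log2 change of TPM + 1 (KD minus DE) of each tested member of 11 gene lists, filled red or blue where the adjusted p over all genes was below 0.05 and open where it was not, with a black bar at the list's median. The definitive endoderm members lie mostly below 0 (18 blue, 0 red) and the pluripotency members mostly above it (13 red, 0 blue), while the primitive streak members spread to both sides.

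The lists of the Activin and Wnt pathways, which the protocol drives, and of BMP and FGF feedback did not pass, and single members did. Of 25 Activin and Nodal genes, GDF3 rose and GSC and CER1 fell (camera adjusted p = 0.274). Of 21 Wnt targets and feedback genes, LGR5 and the secreted antagonist SFRP1 fell and T rose (camera adjusted p = 0.274). SFRP1 went from 535 ± 70.0 to 314 ± 25.2 TPM (SD, n = 3 each). Of 24 BMP and FGF feedback genes, DUSP4 fell from 95.4 ± 10.97 to 46.0 ± 4.86 TPM while DUSP6, a phosphatase of the same family, rose from 59.7 ± 6.84 to 94.7 ± 2.65 TPM. ID2 and GATA2 rose and BMP2 fell in the same list (camera adjusted p = 0.158). With the replicate block over all genes, 2 rose and 7 fell in the Activin and Nodal list, 3 and 7 in the Wnt list and 8 and 5 in the BMP and FGF list. Many of these calls were lost when 1 library was left out, with fewer libraries in the fit. No Activin and Nodal gene fell without DE replicate 1 or 2 or without any one KD library, and 1 fell without DE replicate 3. In the Wnt list none passed without DE replicate 1 or any one KD library, and none fell without DE replicate 2. In the BMP and FGF list none passed without DE replicate 1 or KD replicate 2, only 1 fell without KD replicate 1 or KD replicate 3, and 2 rose and 1 fell without DE replicate 2.

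Of 24 p53 targets, 3 rose and 1 fell. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 2.94 ± 1.08 to 11.7 ± 2.06 TPM (SD, n = 3 each). PHLDA3, an inhibitor of AKT, rose from 3.07 ± 0.603 to 8.25 ± 1.88 TPM and GDF15, a stress-induced cytokine, from 1.35 ± 0.637 to 4.52 ± 0.597 TPM. BTG2, an antiproliferative gene, fell from 106 ± 3.15 to 63.4 ± 5.15 TPM. Adjusted over the list alone 4 rose and 1 fell, and with the replicate block over all genes 10 rose and 2 fell. No member rose without DE replicate 2, KD replicate 1 or KD replicate 2, and 1 rose without DE replicate 1 or KD replicate 3, while none fell without DE replicate 1 or KD replicate 2. The list passed (camera adjusted p = 0.00448), with an adjusted p = 0.994 with an estimated correlation and 0.717 by fry (0.0491 by fry with the replicate block).

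Of 24 epithelial genes, 4 rose and 1 fell. CDH1 (E-cadherin, also expressed by stem cells) rose from 121 ± 7.71 to 219 ± 8.12 TPM (SD, n = 3 each). ST14 and GRHL2 were also among those that rose, and KRT19, a simple epithelial keratin, fell from 186 ± 14.2 to 122 ± 8.12 TPM. With p adjusted over the list alone, 7 rose and 2 fell, and with the replicate block over all genes 7 and 3. A total of 1 rose without DE replicate 1, 2 without KD replicate 1 and none without KD replicate 2, and the call of KRT19 was lost without each single library except DE replicate 3. The list passed narrowly (camera adjusted p = 0.0330), did not pass with the replicate block (camera adjusted p = 0.103), and had an adjusted p = 0.994 with an estimated correlation and 0.543 by fry (0.0491 by fry with the replicate block). It also did not pass under quantile normalization (0.0567), without DE replicate 2 (0.0697) or without replicate 3 of both groups (0.0642).

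The lists of G2 and M phase genes and of hypoxia and glycolysis genes passed although no member did. The 52 G2 and M phase genes had a median log2 change of 0.09 (camera adjusted p = 0.0270) and the 24 hypoxia and glycolysis genes one of 0.18 (camera adjusted p = 0.0348), and both had an adjusted p = 0.994 with an estimated correlation. HK2, a hexokinase, had 17.1 ± 3.89 TPM in DE and 29.9 ± 3.57 TPM in KD (SD, n = 3 each), and PKM, a pyruvate kinase, 669 ± 30.05 and 524 ± 15.4 TPM. Adjusted over the list alone, no G2 and M phase gene passed and 1 hypoxia and glycolysis gene rose and 1 fell. With the replicate block over all genes 10 genes of the second list rose and 2 fell, with a limma adjusted p of 0.00410 for HK2 and 0.0116 for PKM. The first list did not pass without DE replicate 3 (0.186, with its median at -0.0042), without KD replicate 3 (0.0847) or without both (0.136), nor the second without KD replicate 1 (0.0863) or KD replicate 2 (0.0608).

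The remaining lists did not pass by camera with all libraries. Among 10 long noncoding RNAs of endoderm and stem cells, 3 rose and 3 fell, and 1 of those that fell was the knocked-down GATA6-AS1 itself. LINC00261, a neighbour of FOXA2, fell from 37.7 ± 3.91 to 18.6 ± 2.28 TPM (SD, n = 3 each). The median log2 change of this list was -0.19, its mean 0.14 and its camera adjusted p 0.948, and it passed by fry (adjusted p = 0.0190). With the replicate block 4 rose and 5 fell, and none fell without DE replicate 1 or KD replicate 2. BST2 was the one of 17 interferon response genes to pass (3 fell with the replicate block), going from 227 ± 16.9 to 142 ± 15.3 TPM, and that list's median of 0.00 and mean of -0.05 lay on different sides of 0 (camera adjusted p = 0.817). HSPA8 rose and KLF6 fell among 20 heat shock and immediate early genes (camera adjusted p = 0.260; 8 rose and 2 fell with the replicate block). Neither BST2 nor any gene of the heat shock list passed without DE replicate 1 or 2 or without any one KD library. Without the block, no gene passed among those of S phase (camera adjusted p = 0.957), replication-dependent histones (0.986), the unfolded protein response (0.440), cholesterol synthesis (0.629), nuclear-encoded oxidative phosphorylation (0.629), cytosolic ribosomal proteins (0.526), mitochondrially encoded genes (0.621) or small noncoding RNA (0.455). With the replicate block 2 S phase genes fell, 4 unfolded protein response genes rose and 2 fell, 1 cholesterol gene fell, 1 oxidative phosphorylation gene rose and 1 fell, and 1 mitochondrially encoded gene rose. The mitochondrially encoded list passed without DE replicate 3 (camera adjusted p = 0.000156, median log2 change 0.22), and its median was -0.10 without DE replicate 2 and -0.05 without KD replicate 3.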

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

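The alternatives without mitochondrial genes, without replicate 3 of both groups, with voom, and with both an estimated correlation and the replicate block were chosen after the data were seen. No gene among the 579 changed direction in any of the refits that tested it. The groups did not overlap for any of the 579, so only refits that rescaled the values or used voom could have turned a sign. The count of changed genes was 239 (132 higher, 107 lower) without a filter on low values, where 36978 genes were tested, 1735 (860, 875) with quantile normalization, 1743 (876, 867) with median-of-ratios scaling and 2215 (1042, 1173) with the replicate block. It was 1212 (507, 705) without replicate 3 of both groups, 1696 (878, 818) without mitochondrial genes and 1849 (945, 904) with voom on estimated reads. The fits with quantile or median-of-ratios scaling or without mitochondrial genes used the same 17711 genes and model, so their shifts came from the scaling. The cause of the other shifts was not tested. Stricter thresholds left 229 (153, 76) at a log2 change of 1 or more and 106 (73, 33) at an adjusted p of 0.01, by construction. Leaving out 1 library gave from 87 to 610 genes, 61 to 248 higher and 24 to 362 lower, with fewer samples in each fit. Pseudocounts of 0.1 and 0.5, the mean filter, and the fits without trend or with robust variance gave from 489 to 586. GATA6-AS1 changed by -1.38 to -1.11 without single libraries, and lost its call without DE replicate 1 (adjusted p = 0.0717) and without KD replicate 2 (0.0612). GATA6 passed with quantile normalization (-0.65), median-of-ratios scaling (-0.65), the replicate block (-0.66), without replicate 3 of both groups (-0.70), without mitochondrial genes (-0.65), with voom (-0.66) and without DE replicate 3; without single libraries its change ran from -0.79 to -0.57, and its adjusted p over all alternatives from 0.00203 to 0.247. Rescaling hardly moved the log2 change of GATA6, while its limma adjusted p fell, to 0.00678 without mitochondrial genes, so its call depended on the scaling. The cause of its other changes of call was not tested. Of the 30 lists, 0 passed with an estimated correlation, 0 with that and the replicate block, 4 by fry (definitive endoderm, pluripotency, trophoblast and amnion, and the long noncoding RNAs), 7 by fry with the replicate block (the same 4 with yolk sac, p53 and epithelial genes), 8 with voom (collagens and matrix gained) and 6 to 7 without single libraries. Without DE replicate 1 or KD replicate 2, 47 other named genes lost their call, against 28, 3, 32 and 26 without DE replicate 2, DE replicate 3, KD replicate 1 and KD replicate 3. The log2 change turned its sign for MIXL1 without DE replicate 2 (0.0072; -0.11 to 0.0072 without single libraries) and for RPPH1 (1.83, not passing) without KD replicate 1 (-0.17; -0.17 to 3.15), the library that held its high value. For the genes and lists named in the report, the replicate block changed no call other than where the report gives its value. DESeq2 was not run, because the table holds TPM and not counts. The estimated depth limits genes near 1 TPM, which stood for between 11.28 and 16.16 reads of a 2 kb gene.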

Other observations

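The genes and families of this paragraph were chosen after the values were seen, so their counts are given without a test. The families were picked from 16 looked at, and 579 of all 17711 genes passed. Of the families not named below, GATA (3 of 5) and FOX factors (5 of 26) also held calls. Zinc fingers (3 of 430), solute carriers (5 of 244), claudins (1 of 11) and WNT ligands (0 of 7) held few. Of 12 FGF ligands tested, FGF1, FGF4 and FGF19 rose and FGF17 fell, of which FGF4 and FGF17 also belong to the fixed lists. FGF17 was the most abundant of these, at 2105 ± 17.3 TPM in DE and 1388 ± 80.7 TPM in KD (SD, n = 3 each). The basic helix-loop-helix repressors HES3, HEY1 and HEY2 rose, 3 of 7 tested, as did the synaptotagmins SYT1, SYT6 and SYT7, 3 of 11. Of 19 semaphorins, SEMA6A rose and SEMA3E, SEMA5B and SEMA6D fell. PIK3R5 and PIK3R6, regulatory subunits of PI3K gamma that lie side by side on chromosome 17, fell from 70.6 ± 4.51 to 33.8 ± 3.46 TPM and from 10.99 ± 1.12 to 4.40 ± 0.871 TPM. Each FGF, HES, HEY, SYT, SEMA and PIK3R gene named here kept its direction in the alternatives that tested it, but not always its call. For these genes the groups did not overlap, so only rescaling or voom could have turned the direction. SYT7 passed in 10 of 18 alternatives, SEMA5B in 11 of 18, SEMA6D in 12 of 18, and FGF1 and HEY1 in 11 of 17, while SYT6, SEMA6A, SEMA3E and PIK3R5 passed in all 18 and the others named here in 13 to 16.

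Single genes of known function also changed, and PDGFA, POLR3G, NTS and ACKR3 were likewise chosen after the values were seen. PDGFA, a growth factor, rose from 10.4 ± 1.34 to 38.1 ± 3.90 TPM (SD, n = 3 each). POLR3G, an RNA polymerase III subunit of pluripotent cells, rose from 13.6 ± 1.45 to 49.0 ± 7.08 TPM, and NTS, the neurotensin gene, from 43.0 ± 6.74 to 126 ± 7.15 TPM. ACKR3, a scavenger receptor for the ligand of CXCR4, fell from 111 ± 16.2 to 54.0 ± 6.70 TPM. It passed in 15 of 18 alternatives, and PDGFA, POLR3G and NTS passed in all 18. KD replicate 1 held 99.5 TPM of RPPH1, 47.2 TPM of RN7SK and 11.3 TPM of RMRP, RNAs made by RNA polymerase III, against at most 1.53, 22.1 and 3.49 TPM in any other library. The clone-named gene AL353644.11 stood at 3356 TPM in the same library and at 26.7 TPM or less in the others. The median log2 change per chromosome lay between -0.04 and 0.03 over 23 chromosomes.

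The tests of explanations in this part, except the counts over other splits, were chosen after the data were seen. The joint fall of endoderm genes and rise of pluripotency genes in KD may come from the knockdown, from a different mix of cells, or from a construct or its delivery, which could not be tested because the labels name no control construct in the wild-type cells. Undifferentiated cells diluting otherwise unchanged endoderm would lower MIXL1 with the rest. On the log2 scale MIXL1 moved by 0.65 against the mean of SOX17, FOXA2, CXCR4, GATA4, EOMES, GSC and CER1 (SE 0.0575, 95% interval 0.49 to 0.81, exact permutation p = 0.1, the smallest possible). MIXL1 was set apart after its nearly unchanged value was seen, so this contrast could not decide on dilution. It shows only that MIXL1 did not fall with the mean of the others in these libraries. A culture held at the earlier primitive streak stage stayed open, since the streak list moved both ways (camera adjusted p = 0.957). Of the 10 splits of the libraries, 1 called 579 genes or more and the highest other called 1, while 2 passed 7 lists or more with 7 as the highest other, and 10 splits are too few for a share under 0.05. The 3 other splits that also part every replicate pair called 0 genes by limma and 2 to 5 lists by camera with its preset correlation. They held 203 to 254 genes at an unadjusted limma p under 0.05, against 2731 for KD and DE. The 6 splits that part 1 pair held 204 to 2591. The camera adjusted p of the endoderm list went down to 9.34e-09 in the 3 splits. Each side of these mixed splits held 2 libraries of 1 group and 1 of the other, so part of the difference between KD and DE remained. Their passing lists therefore cannot show whether camera passes lists without an effect.

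Replicate 3 of both groups stood apart from the other libraries. With group in the model, 6670 genes differed between the third and the other replicates, 255 higher and 6415 lower, beside the larger mitochondrial share. With TPM recomputed without mitochondrial genes 2603 differed, 829 higher and 1774 lower, so the mitochondrial share could account for a large part of the gap, and the rest stayed open. The same share does not account for the difference between KD and DE, for which 1696 genes passed after the same step against 579 before. No biological explanation was tested, since the labels give the third replicates no other treatment.

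Genes of the imprinted DLK1 to DIO3 cluster on chromosome 14 (GRCh38, 100725705 to 101563452) were lower in KD. All 4 tested members other than microRNAs fell and kept this direction in the alternatives that tested them (past the threshold in 11 of 17 for MEG9, 11 of 18 for DIO3OS and 14 of 18 for DLK1), DLK1 (log2 change -1.16), MEG9 (-1.08), DIO3OS (-0.85) and DIO3 (-1.20), the last from 92.9 ± 8.18 to 39.6 ± 0.816 TPM (SD, n = 3 each), with DIO3OS and DIO3 as close neighbours on opposite strands. The groups did not overlap for any of these 4 genes, so only rescaling or voom could have turned their direction. Of the 20 nearest protein-coding genes 1 passed, and their median log2 change was -0.0474 (95% bootstrap interval -0.13 to 0.06). This argued against loss of a wider chromosome segment reaching past the cluster on both sides. The median took both sides together, so a loss reaching into 1 side only could not be judged. A chance run of neighbours stayed open: no other of 14215 windows of 4 neighbouring genes had a median as far from 0, but 6.3% of 2000 shuffled gene orders held one. A change of imprinting in the cluster is a hypothesis that TPM cannot test, and of 15 imprinted genes elsewhere none passed (6 with the replicate block).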
